A study of Homo sapiens with 30 samples.

How the data were processed

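The series holds 30 samples of the human breast cancer cell line T47D, passages 18 to 20. The 12 RNA-seq libraries were used, in 6 groups of 2, and the 18 ChIP-seq samples were not analysed here because no ChIP file was at hand. Groups were taken from the sample titles. They are siControl untreated, siControl progestin, siCEBPA untreated, siCEBPA progestin, ICRF untreated and ICRF progestin. Progestin means R5020 at 10 nM, and the siRNA libraries had a short arrest of 4 hours before hormone, per the labels' protocols. Untreated siRNA libraries have the time label T0 and progestin siRNA libraries T360, without a unit. The ICRF libraries have no time label.

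The deposited values are raw read-pair counts per gene, made by featureCounts 1.5.1 in paired mode with reverse-strand counting on GENCODE 24 genes and the build hg38, per the file headers. The assembly folder named there is hg38_mmtv, and what was added to hg38 was not examined. The counts came from STAR alignments, per the file headers, and the submitters' processing notes name Trimmomatic and STAR without versions. No option for reads with several alignments was set, per the file headers, so genes with near-identical copies are uncertain. Each file held 60554 genes, of which 56558 (93.4%) had a symbol, and these held 99.85% of all counts. Library totals ran from 57364785 to 148624099.

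Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr and scaled with TMM factors, and the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) was applied with Benjamini-Hochberg adjustment and a threshold of adjusted p of 0.05. The standard error of a log2 fold change was its size over the square root of F. One fit held the 8 siRNA libraries (18351 genes, 4 residual degrees of freedom, common biological coefficient of variation 0.0509), another the 4 ICRF libraries (18556 genes, 2 residual degrees of freedom, 0.0362) and another all 12 (19003 genes, 6 residual degrees of freedom, 0.0464). The hormone response was tested in siControl, in siCEBPA and with ICRF, the knockdown in untreated and in treated cells, and the difference of responses for siCEBPA against siControl and for ICRF against siControl. The labels do not say whether replicates were separate cultures, so every p measures the spread between these libraries, which may be technical. Pearson correlations of log2 CPM between the replicates of a group ran from 0.9985 to 0.9992, and the mean chi-square per gene between them from 4.6 to 14, above the value of 1 that counting noise alone would give.

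The 17 gene lists were fixed before the data were examined. They are progestin-induced, oestrogen-responsive, DNA replication and G1/S, mitosis and G2/M, cell cycle inhibitor and antiproliferative, p53 target, C/EBP family and Tribbles, fatty acid synthesis and fat storage, cholesterol synthesis and uptake, interferon-stimulated, immediate early, unfolded protein and amino acid stress, luminal epithelial, basal and myoepithelial, and fibroblast, endothelial and blood cell genes, chromatin factors and cohesin genes, and mitochondrially encoded messenger RNAs. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The run with an estimated correlation also takes its p from the residual degrees of freedom of the fit (4, 2 or 6). It therefore has little power here, and a list that misses the threshold under it is not shown to be unchanged. Some genes are in several lists, so the lists are not independent. Examples are DDIT3 and TRIB3 (C/EBP family and stress) and CDKN1A (progestin-induced, inhibitor and p53). Members past the threshold were counted over all genes and adjusted over the list alone. Genes called for the hormone under ICRF were tested as sets in the siRNA libraries with fry, adjusted over the 2 sets, and with camera. Genes to name were, by a rule fixed in advance, the 8 largest rises and the 8 largest falls with a mean of at least 5 CPM in 1 of the groups compared and no overlap between the libraries of the groups, the 4 members of each list with the smallest p, and CEBPA, PGR, TOP2A, TOP2B, RAD21, CCND1 and CDKN1A. The demand of no overlap was not made for the differences of responses. The texts name a part of the genes so taken, picked after their values were seen. Genes without a usual symbol were left out of the naming, and a few genes that the rule takes are not reported here.

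The steps were tested on simulated counts for the real genes with 200 changed genes in each comparison. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of lower tested genes was not measured. Of genes changed 1.5-fold, 76.1% to 91.0% were recovered, of those changed 2-fold 91.0% to 100%, and of those changed 4-fold 98.5% to 100%, while 0.078% to 0.153% of unchanged genes were called. In the same simulation camera at the preset correlation called 1 of the 16 lists not changed as a whole in 4 of the 7 comparisons, where single members could be among the changed genes. The simulation drew genes independently and changed far fewer of them than the 1329 to 11385 called in the real comparisons. It therefore does not test scaling under widespread change, nor camera with correlated genes. Alternatives tried were other scaling factors, other filters on low counts, DESeq2 1.42.0, a minimum fold, other sets of libraries in the fit, each replicate left out, and the replicate number as a block. Added after seeing the data were no scaling factors, counts thinned to the shallowest library, both siCEBPA libraries numbered 2 left out, and CEBPA left out of the C/EBP family list.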

Results

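Gene expression was measured by RNA-seq in T47D cells, a human luminal breast cancer line rich in progesterone receptor, the hormone-activated transcription factor encoded by PGR. The 12 libraries formed 6 groups of 2. Cells transfected with a control siRNA (siControl) or with an siRNA against CEBPA (siCEBPA) were untreated or treated with progestin, which made 8 libraries. Cells labelled ICRF, untreated or treated with progestin, made 4 libraries. The labels do not explain this name, which usually denotes an inhibitor of DNA topoisomerase II. Nor do the labels state that these libraries came from a separate experiment. They were taken as one because their titles name no siRNA, arrest or time. The progestin was the synthetic agonist R5020 at 10 nM. All untreated siRNA libraries carried the time label T0 and all progestin siRNA libraries T360, with no unit. No untreated library was labelled T360, so hormone changes in the siRNA libraries cannot be told apart from changes with the time label. The ICRF libraries carried no time label. The total count per library ran from 57364785 to 148624099. The ICRF libraries held 103156070 to 108066269. Among the siRNA libraries siControl untreated replicate 2 held 148624099, and the next deepest held 70704799. Expression levels are in CPM with TMM scaling, given as mean ± SD over n = 2 libraries. Changes are log2 fold changes ± SE from edgeR, with n = 2 libraries in each group, and every change named below had an adjusted p under 0.05 unless its p is given as having missed it. Largest rises and falls are named among genes with a symbol and a mean of at least 5 CPM. Positions are on the human genome build hg38.

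CEBPA encodes the transcription factor C/EBPα, was the target of the siRNA, and is a gene with 1 exon on chromosome 19 from 33299934 to 33302564. Its level was 50.9 ± 4.76 CPM in siControl untreated cells and 203 ± 2.00 CPM in siControl progestin cells. In siCEBPA cells it was 11.4 ± 0.958 CPM untreated and 59.7 ± 3.01 CPM with progestin. The log2 change of CEBPA after the siRNA was -2.16 ± 0.07 without hormone (adjusted p = 2.75e-11) and -1.76 ± 0.06 with hormone (adjusted p = 7.52e-11). Progestin raised CEBPA by 1.99 ± 0.07 in siControl cells and by 2.39 ± 0.07 in siCEBPA cells, and the level in siCEBPA progestin cells lay above that in siControl untreated cells by 0.23 ± 0.06 (adjusted p = 0.00681). With ICRF, CEBPA stood at 38.7 ± 0.253 CPM untreated and 88.7 ± 1.67 CPM with progestin, a rise of 1.20 ± 0.04.

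**Figure D1:**
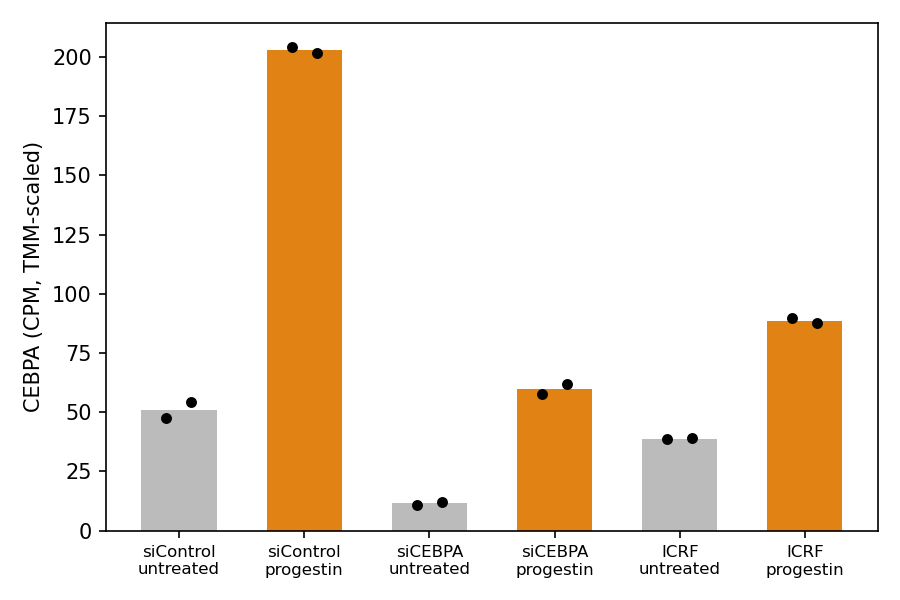
CEBPA level in each library (points, TMM-scaled CPM, linear axis from 0) with the mean of each group (bar, n = 2 libraries per group). Progestin groups lie above the untreated group of the same treatment, from 50.9 to 203 in siControl, 11.4 to 59.7 in siCEBPA and 38.7 to 88.7 with ICRF.

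The comparison of siControl progestin with siControl untreated asked how expression differed with hormone, and with the time label, in cells without CEBPA siRNA. TSC22D3, which encodes the leucine zipper protein GILZ, rose from 38.6 ± 1.12 to 628 ± 22.2 CPM (log2 4.02 ± 0.05, adjusted p = 5.71e-17), and FKBP5, a co-chaperone of steroid receptors, rose from 81.1 ± 3 to 507 ± 17.2 CPM (log2 2.65 ± 0.04). The receptor gene PGR itself, on chromosome 11 from 101029624 to 101130524, fell from 977 ± 10.2 to 272 ± 6.07 CPM (log2 -1.84 ± 0.04, adjusted p = 1.86e-15). FOXA1, a pioneer transcription factor of luminal cells, fell (-2.60 ± 0.05). The largest rises included those of ZBTB7C, a zinc finger protein (6.43 ± 0.13), CAVIN2, a coat protein of caveolae (5.78 ± 0.19), KCNC1, a voltage-gated potassium channel (4.91 ± 0.11), and SCNN1G, a subunit of the epithelial sodium channel (4.80 ± 0.18). The largest falls included those of RBBP8NL (-4.21 ± 0.12), RIPOR3 (-3.85 ± 0.13), the adhesion protein AMIGO2 (-3.79 ± 0.09) and the cytokine TNFSF15 (-3.59 ± 0.16).

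Of the 31 measured progestin-induced genes, 25 rose and 3 fell in siControl cells, or 26 and 3 adjusted over the list alone, among them PDK4, a kinase that restrains pyruvate oxidation (3.37 ± 0.09), and the phosphatase DUSP1 (2.39 ± 0.07). The list stood above other genes (camera, adjusted p = 3e-23) and kept this with an estimated correlation (adjusted p = 0.00526). Among 30 mitosis and G2/M genes, 28 fell and none rose, also adjusted over the list alone, including CKAP2L (-1.16 ± 0.08), the spindle protein ASPM (-0.87 ± 0.06), the proliferation marker MKI67 (-0.53 ± 0.05) and TOP2A (-0.56 ± 0.06), which encodes topoisomerase II alpha. The camera adjusted p was 1.11e-05, and the adjusted p with an estimated correlation was 0.729. Among 33 DNA replication and G1/S genes, 20 fell, among them the helicase subunit MCM7 (-0.54 ± 0.05) and the transcription factor E2F1 (-0.81 ± 0.07), and 4 rose, among them GINS2 (1.32 ± 0.06), with the same counts adjusted over the list alone (camera, adjusted p = 0.0257, and adjusted p = 0.961 with an estimated correlation). Cell cycle inhibitors and antiproliferative genes went both ways, with 9 of 17 higher and 7 lower, also adjusted over the list alone (camera, adjusted p = 0.918). CDKN1C, which encodes p57, rose from 0.109 ± 0.0525 to 4.12 ± 0.19 CPM (5.07 ± 0.23), BTG2 rose (1.75 ± 0.07), CDKN1A, which encodes p21, rose (0.44 ± 0.04), and TXNIP fell (-1.30 ± 0.04). CCND1, the gene of cyclin D1, rose by 0.43 ± 0.05, and the cohesin subunit gene RAD21 fell (-0.33 ± 0.05).

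Of 21 cholesterol synthesis and uptake genes, 15 rose and 3 fell, also adjusted over the list alone, with DHCR7 (1.63 ± 0.05) and SQLE (1.30 ± 0.05), both enzymes of the pathway, among the rises (camera, adjusted p = 4.92e-05, and adjusted p = 0.273 with an estimated correlation). Of 21 fatty acid synthesis and fat storage genes, 11 rose and 7 fell, also adjusted over the list alone, led by ACSL1 (1.55 ± 0.04) and the desaturase SCD (1.22 ± 0.05), with a camera adjusted p of 0.0257 and an adjusted p of 0.273 with an estimated correlation, and the list median of 0.15 was -0.01 with no scaling factors. Of 25 oestrogen-responsive genes 12 fell and 7 rose (12 and 8 adjusted over the list alone), with the chemokine CXCL12 (-2.12 ± 0.05) and IGFBP4 (-1.93 ± 0.05) among the falls (camera, adjusted p = 0.00029, and adjusted p = 0.273 with an estimated correlation). Of 16 luminal epithelial genes 10 fell and 3 rose, also adjusted over the list alone, among them ELF3 (-1.71 ± 0.06) and KRT18 (-0.65 ± 0.04) down and CLDN4 up (0.85 ± 0.04). Camera gave adjusted p = 0.00189, and adjusted p = 0.273 with an estimated correlation. Of 8 C/EBP family and Tribbles genes 6 rose and 1 fell, also adjusted over the list alone, with CEBPD (2.10 ± 0.19) and CEBPB (0.86 ± 0.08) rising besides CEBPA (camera, adjusted p = 0.0126, adjusted p = 0.273 with an estimated correlation, and adjusted p = 0.17 with CEBPA left out of the list). TOP2B did not pass the test (-0.03 ± 0.05, adjusted p = 0.622). Over all 18351 genes tested, 5367 were higher and 5374 lower with hormone, and 3039 of these changed at least 2-fold. The share of higher calls, 50.0%, was 38.2% with upper quartile scaling, under which the median of all genes was -0.14 against -0.03, and 33.9% with no scaling factors (median -0.19). No call shared between settings changed sign.

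The same contrast was made in siCEBPA cells. PGR fell from 849 ± 7.92 to 381 ± 6.63 CPM (log2 -1.15 ± 0.04, adjusted p = 2.91e-13), TSC22D3 rose by 3.93 ± 0.06 and FKBP5 by 2.35 ± 0.04. ZBTB7C (6.93 ± 0.13), CDKN1C (6.34 ± 0.25), the desmosome protein PKP1 (6.11 ± 0.12) and the secreted peptide APLN (5.91 ± 0.21) had some of the largest rises. DUSP6, a phosphatase that inactivates ERK (-4.67 ± 0.13), EGR1, an immediate early transcription factor (-4.29 ± 0.19), RBBP8NL (-4.15 ± 0.12) and LRRK2 (-3.09 ± 0.10) had some of the largest falls. CCND1 rose by 0.84 ± 0.05 and CDKN1A by 0.70 ± 0.04, while TOP2A changed by -0.34 ± 0.06 and RAD21 by -0.23 ± 0.05. TOP2B gave -0.01 ± 0.05 and missed the threshold (adjusted p = 0.882). Of 31 progestin-induced genes 28 rose and 2 fell, also adjusted over the list alone, with NDRG1 (3.65 ± 0.08) and PDK4 (3.98 ± 0.10) among the rises (camera, adjusted p = 1.84e-27, and adjusted p = 0.00378 with an estimated correlation). Of 30 mitosis and G2/M genes 22 fell and 1 rose (23 and 1 adjusted over the list alone), such as ASPM (-0.75 ± 0.06) and CENPE (-0.61 ± 0.06). The camera test gave adjusted p = 0.00503, and adjusted p = 0.949 with an estimated correlation. The lists of oestrogen-responsive (8 up, 13 down of 25), luminal (4 up, 10 down of 16), cholesterol (13 up, 4 down of 21) and C/EBP family genes (5 up, 1 down of 8) also passed camera, with adjusted p of 0.0174, 0.00503, 0.0064 and 0.00367. Adjusted over the list alone these counts were 8 and 13, 5 and 10, 13 and 5, and 5 and 1. With an estimated correlation the adjusted p of these 4 lists were 0.413, 0.384, 0.521 and 0.384, and the C/EBP family list had adjusted p = 0.0523 by camera with CEBPA left out.

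In all, 5482 genes were higher and 5203 lower with hormone in siCEBPA cells, of which 3062 changed at least 2-fold. The share of higher calls was 51.3%, against 36.9% with upper quartile scaling (median of all genes -0.16 against -0.03) and 33.3% with no scaling factors (median -0.19). Hormone changes in siControl and siCEBPA cells, which share no library, had 8836 genes called in both, 8751 with the same sign and 85 with opposite signs. Both were higher for 4565 genes and both lower for 4186, where independent lists of these sizes would share 1603 and 1524. Across the 18351 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.863 and a Spearman correlation of 0.842.

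The knockdown itself was compared in untreated and in progestin-treated cells, to ask what CEBPA siRNA changed at each hormone state. TFF1, a secreted trefoil peptide and oestrogen target, changed by -2.41 ± 0.12 without and -2.40 ± 0.12 with hormone, and LCN2, which encodes lipocalin-2, by -2.27 ± 0.23 and -2.49 ± 0.24. CHAC1, a glutathione-degrading enzyme induced by amino acid stress (-2.57 ± 0.10), and the stress cytokine GDF15 (-2.20 ± 0.15) had some of the largest falls in untreated cells. The protease inhibitor SLPI had the largest fall in progestin-treated cells, from 24.3 ± 0.365 to 2.03 ± 0.383 CPM (-3.58 ± 0.12, adjusted p = 1.18e-11). Large rises included those of the zinc finger pseudogene ZNF702P (2.43 ± 0.09, uncertain because reads shared with related zinc finger genes may be split), the cation channel TRPM8 (2.42 ± 0.13) and the phospholipase PLCE1 (2.08 ± 0.07) in untreated cells, and of the axon guidance receptor ROBO2 (2.22 ± 0.13), PERP, a desmosome-associated protein (2.16 ± 0.06), and SCARA3 (2.03 ± 0.08) in treated cells. MRPL34 (-2.25 ± 0.11) and ABHD8 (-2.24 ± 0.14) also fell in untreated cells and overlap on opposite strands of chromosome 19, where counting used the strand. IGFBP4, a binding protein of insulin-like growth factors, was higher without (0.95 ± 0.05) and with hormone (1.91 ± 0.05). PGR was -0.20 ± 0.04 without and 0.49 ± 0.04 with hormone, CDKN1A -0.70 ± 0.04 and -0.44 ± 0.04, and TOP2B 0.25 ± 0.05 and 0.27 ± 0.05. TOP2A was 0.03 ± 0.06 without hormone, short of the threshold (adjusted p = 0.683), and 0.25 ± 0.06 with it, which missed the threshold without siControl progestin replicate 1 (adjusted p = 0.0605). CCND1 was -0.38 ± 0.05 without hormone and 0.04 ± 0.05 with it (adjusted p = 0.571, not past the threshold). RAD21 was -0.20 ± 0.05 without hormone (adjusted p = 0.0842 with no scaling factors) and -0.10 ± 0.05 with it (adjusted p = 0.121, not past the threshold).

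Among 19 unfolded protein and amino acid stress genes, 15 fell and 1 rose after CEBPA siRNA in untreated cells, and 17 fell and none rose in treated cells, also adjusted over the list alone. ATF4, the transcription factor of the amino acid response (-0.78 ± 0.05 untreated), DDIT4 (-1.45 ± 0.06 and -1.02 ± 0.06), the serine synthesis enzyme PSAT1 (-0.75 ± 0.04 and -0.70 ± 0.05) and the chaperone DNAJB9 (-0.80 ± 0.06 treated) were among them. The list medians were -0.59 and -0.60 (camera, adjusted p = 1.06e-12 and 5.5e-14). With an estimated correlation the adjusted p were 0.118 and 0.202. Besides CEBPA, the target of the siRNA, the 7 other measured C/EBP family and Tribbles genes were all lower in untreated cells and 6 in treated cells, also adjusted over the list alone, with CEBPB at -1.45 ± 0.09 and -0.90 ± 0.08 and DDIT3 at -0.73 ± 0.07 and -0.67 ± 0.07 (camera without CEBPA, adjusted p = 9.97e-05 and 0.00424, and adjusted p = 0.144 and 0.283 with an estimated correlation). DDIT3 and TRIB3 are also members of the stress list, so the falls of these lists are not separate results. Of 19 p53 target genes 9 fell and 2 rose without hormone and 9 fell and 3 rose with it, also adjusted over the list alone, such as SESN2 (-0.91 ± 0.06) and AEN (-0.67 ± 0.05 and -0.69 ± 0.05), with camera adjusted p of 0.00288 and 0.0347 and adjusted p of 0.116 and 0.209 with an estimated correlation. Of 31 progestin-induced genes 17 fell and 7 rose without hormone, also adjusted over the list alone, among them S100P (-2.14 ± 0.08). By camera the list had adjusted p = 0.00471, and adjusted p = 0.116 with an estimated correlation. Of 21 cholesterol genes 10 rose and 3 fell without hormone (11 and 3 adjusted over the list alone), with MVK (0.49 ± 0.05) and STARD4 (0.62 ± 0.06) up. Camera gave adjusted p = 0.0334, and adjusted p = 0.657 with an estimated correlation. Of 12 basal and myoepithelial genes 5 rose and 1 fell without hormone and 6 rose and 1 fell with it (5 and 1, then 6 and 2, adjusted over the list alone). The cadherin CDH3 (0.82 ± 0.04 and 1.28 ± 0.04) and the laminin chain LAMB3 (1.22 ± 0.12 and 1.55 ± 0.14) were among the rises, with camera adjusted p of 0.0393 and 0.00424 and adjusted p of 0.212 and 0.209 with an estimated correlation. Of 16 luminal genes 1 rose and 8 fell without hormone and 6 rose and 7 fell with it (2 and 8, then 7 and 7, adjusted over the list alone), with CLDN4 (-0.54 ± 0.04 and -0.84 ± 0.04) and ERBB3 (-0.25 ± 0.04 and -0.64 ± 0.04) among the falls, and the list did not pass camera (adjusted p = 0.0678 and 0.19). Mitosis and G2/M genes went both ways without hormone (7 up, 8 down of 30). With hormone 13 of the 30 were higher and 2 lower (15 and 2 adjusted over the list alone), with KIF23 among the higher (0.42 ± 0.05), and the rest did not pass. The camera adjusted p were 0.903 and 0.0144, the latter 0.752 as an adjusted p with an estimated correlation. In treated cells 11 of 23 immediate early genes fell and 4 rose, also adjusted over the list alone, with MYC (-0.53 ± 0.05) down and the matricellular gene CCN1 up (1.32 ± 0.07), and the list did not pass camera (adjusted p = 0.175). Of 10 measured fibroblast, endothelial and blood cell genes 4 rose and none fell in untreated cells, and 2 rose and none fell in treated cells, also adjusted over the list alone (camera, adjusted p = 0.423 and 0.23). The collagen-binding proteoglycan LUM went from 1.7 ± 0.223 to 3.32 ± 0.226 CPM untreated and from 1.03 ± 0.13 to 3.37 ± 0.158 CPM with hormone.

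**Figure D2:**
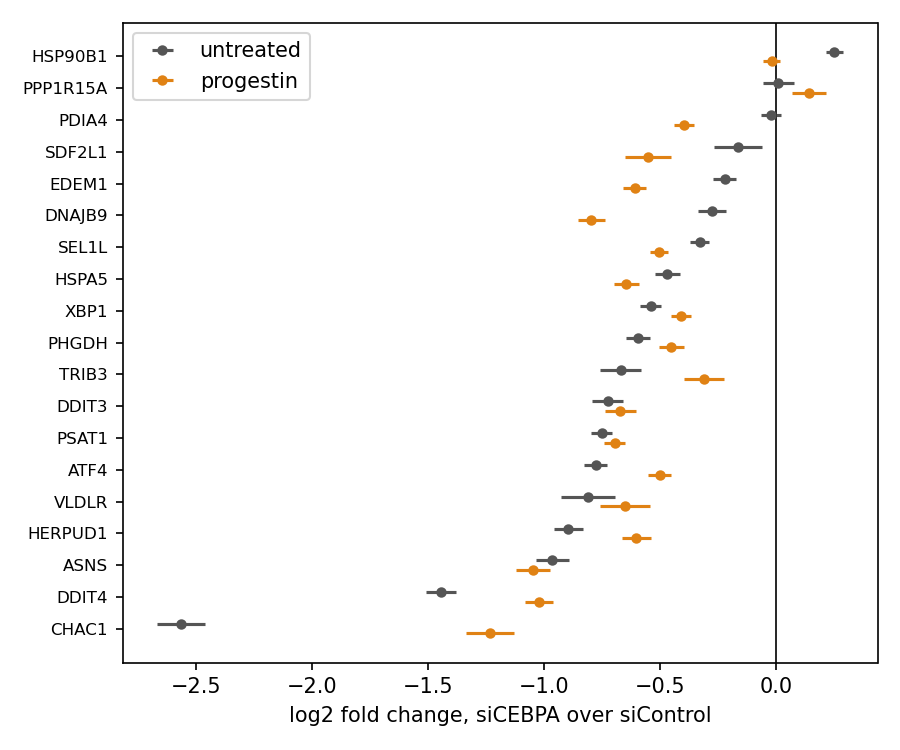
Log2 fold change after CEBPA siRNA of each of the 19 unfolded protein and amino acid stress genes (vertical axis) in untreated and in progestin-treated cells, with bars of 1 SE from edgeR. Points left of 0 are lower in siCEBPA, and the list medians are -0.59 and -0.60.

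Interferon-stimulated genes set the siCEBPA replicates apart. All 28 members were higher in siCEBPA replicate 2 than in replicate 1, by a median log2 of 0.91 untreated and 0.83 with progestin, while the medians of replicate 2 over 1 were -0.03 and -0.23 in the siControl groups. IFIT1, an antiviral RNA-binding protein, was at 77.9 and 187 CPM in the siCEBPA untreated replicates and at 57.9 and 51.6 CPM in the siControl untreated replicates. In the knockdown comparisons 2 of the 28 rose without hormone (1 adjusted over the list alone) and 1 rose and 1 fell with it, also adjusted over the list alone (camera, adjusted p = 0.253 and 0.69). In all, 4153 genes were higher and 4405 lower after CEBPA siRNA in untreated cells, and 4133 higher and 4059 lower in treated cells, of which 1248 (846 higher and 402 lower) and 1209 (865 higher and 344 lower) changed at least 2-fold. Leaving out both siCEBPA libraries numbered 2 gave 7446 and 7566 calls in place of 8558 and 8192. The shares of higher calls, 48.5% and 50.5%, were 48% and 48.9% with RLE scaling, and 65.3% and 64.9% with no scaling factors, under which the median of all genes was 0.10 and 0.11 against 0.01 and 0.02.

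The test of the difference between the hormone changes of siCEBPA and siControl cells asked where CEBPA siRNA altered the response. The fall of PGR was smaller in siCEBPA cells by 0.69 ± 0.05 (adjusted p = 1.44e-06), and the rise of DUSP1 was smaller by a log2 difference of -1.34 ± 0.09 (adjusted p = 7.1e-07), from 8.66 to 45.3 CPM in siControl and from 9.95 to 20.6 CPM in siCEBPA cells. The largest negative difference was that of NES, which encodes the intermediate filament protein nestin (-2.70 ± 0.21), followed by the chromatin factor ARID5B (-1.65 ± 0.10). DUSP6 (-1.45 ± 0.19) and SPRY2 (-1.26 ± 0.13), both feedback inhibitors of ERK signalling, and the ephrin gene EFNA3 (-1.35 ± 0.08) were also among the negative differences. The largest positive differences were those of GABRQ, a GABA receptor subunit (2.04 ± 0.24), the metalloreductase STEAP4 (1.94 ± 0.14) and PKP1 (1.91 ± 0.18). CCND1 had a larger rise in siCEBPA cells (0.42 ± 0.07). The differences of CDKN1A (0.26 ± 0.06) and CEBPA (0.40 ± 0.10) were positive too, but both missed the threshold without siControl untreated replicate 2 (adjusted p = 0.0707 and 0.0635), siControl progestin replicate 1 (0.0807 and 0.0992) or 2 (0.0551 and 0.0887), and that of CEBPA also without siCEBPA untreated replicate 1 (0.115) or siCEBPA progestin replicate 2 (0.0507). TOP2A (0.22 ± 0.09, adjusted p = 0.179), TOP2B (0.02 ± 0.07, adjusted p = 0.923) and RAD21 (0.10 ± 0.07, adjusted p = 0.492) did not pass.

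Of 25 oestrogen-responsive genes 10 had a positive and 3 a negative difference (10 and 4 adjusted over the list alone), with IGFBP4 (0.96 ± 0.07) and RERG (0.68 ± 0.08) among the positive ones (camera, adjusted p = 0.000184, and adjusted p = 0.321 with an estimated correlation). Of 31 progestin-induced genes 10 were positive and 4 negative (11 and 5 adjusted over the list alone), with NDRG1 (1.41 ± 0.11), S100P (1.31 ± 0.11) and the kinase SGK1 (1.60 ± 0.22) positive. The camera test gave adjusted p = 0.0107, and adjusted p = 0.321 with an estimated correlation. A positive difference is one of change and not of level. With hormone S100P stood at 195 CPM in siCEBPA and 348 CPM in siControl cells, from 8.84 and 38.8 CPM untreated. NDRG1 stood at 70.8 and 44.6 CPM with hormone, and SGK1 at 4.67 and 2.67 CPM. The mitosis and G2/M list had a median difference of 0.18, with 2 of 30 genes past the threshold, KIF23 (0.35 ± 0.07) and MKI67 (0.25 ± 0.07), also adjusted over the list alone (camera, adjusted p = 4.46e-05, and adjusted p = 0.725 with an estimated correlation). Neither gene passed without siControl progestin replicate 1 (adjusted p = 0.0563 and 0.203), nor MKI67 without siControl untreated replicate 1 (0.0906) or siCEBPA untreated replicate 2 (0.1). DNA replication and G1/S genes had a median of 0.16 and 3 of 33 positive (6 adjusted over the list alone), among them UHRF1 (0.58 ± 0.12) and RRM2 (0.41 ± 0.09), both of which missed the threshold without siControl progestin replicate 1 (adjusted p = 0.0625 and 0.0651). By camera the list had adjusted p = 0.00127, and adjusted p = 0.725 with an estimated correlation. Cholesterol genes had a negative difference in 5 of 21 and a positive one in none (7 and 1 adjusted over the list alone), such as STARD4 (-0.53 ± 0.08) and DHCR7 (-0.41 ± 0.07). Camera gave adjusted p = 0.000153, and adjusted p = 0.557 with an estimated correlation. C/EBP family genes were positive in 3 of 8 (5 positive and 2 negative adjusted over the list alone), with CEBPG (0.46 ± 0.07) and CEBPB (0.55 ± 0.12) besides CEBPA, and a camera adjusted p of 0.0274 (adjusted p = 0.564 with an estimated correlation, and 0.102 with CEBPA left out of the list). CEBPB missed the threshold without siControl untreated replicate 2 (adjusted p = 0.0509) or siControl progestin replicate 2 (0.0607). Immediate early genes were negative in 4 and positive in 2 of 23 (6 and 2 adjusted over the list alone), with FOS negative (-1.48 ± 0.30) and KLF6 positive (0.57 ± 0.08). The camera test gave adjusted p = 0.0375, and adjusted p = 0.725 with an estimated correlation. In all, 1329 genes passed, 768 with a positive and 561 with a negative difference, and 129 differed at least 2-fold, 87 of them positive and 42 negative. The share of positive differences, 57.8%, was 49.7% with upper quartile scaling (684 positive and 693 negative). The count was 692 without siControl progestin replicate 1 and 779 without siControl progestin replicate 2.

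Genes called in the ICRF experiment served as a choice of hormone genes made on other libraries. The 5628 genes that were higher with hormone under ICRF and tested in the siRNA libraries had a median log2 change of 0.19 in siControl and 0.18 in siCEBPA cells, and the 5472 that were lower had medians of -0.24 and -0.20. A change of the same sign was found for 66.3% of the higher genes in siControl and 65.7% in siCEBPA cells, and for 68.6% and 65.7% of the lower genes. The rest went the other way, so these sets do not share 1 response. Slopes through 0 of the siCEBPA on the siControl changes were 1.02 for the higher and 0.837 for the lower genes. With 1 library left out these slopes ran from 0.928 to 1.048 and from 0.719 to 0.891. The median difference of the responses was 0.01 for the higher genes (fry, adjusted p = 0.403) and 0.05 for the lower genes (fry, adjusted p = 0.0162). Neither set passed camera at the preset correlation, which compares a set with the other genes (p = 0.742 and 0.111 before adjustment). For the higher genes the median difference was -0.004 with a mean of at least 5 CPM and 0.08 for those that changed at least 2-fold (fry, adjusted p = 0.000199). These 2-fold genes did not pass camera at the preset correlation (p = 0.119 before adjustment), and the median difference of all genes was 0.02. For the lower genes the fry result did not stay under 0.05 without siControl progestin replicate 1 (adjusted p = 0.141), siCEBPA untreated replicate 1 (adjusted p = 0.0714) or 2 (adjusted p = 0.0852), siCEBPA progestin replicate 2 (adjusted p = 0.0796) or ICRF progestin replicate 1 (adjusted p = 0.05), nor by camera with an estimated correlation (adjusted p = 0.0946).

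The ICRF experiment asked how progestin changed expression with ICRF present. ESR1, the oestrogen receptor gene, went from 172 ± 6.79 to 27.1 ± 0.281 CPM (log2 -2.66 ± 0.04, adjusted p = 4.51e-40), the luminal transcription factor SPDEF fell (-2.93 ± 0.05), and PGR fell from 973 ± 2.43 to 254 ± 4.67 CPM (-1.94 ± 0.03). The largest fall among the genes the naming rule takes was that of LIN28A, an RNA-binding protein (-4.05 ± 0.08). SCNN1G (5.04 ± 0.20), ZBTB7C (4.65 ± 0.15), the co-chaperone DNAJB4 (4.24 ± 0.05) and NDRG1 (3.99 ± 0.07) had some of the largest rises. TOP2A, on chromosome 17 from 40388516 to 40417950, rose from 1252 ± 12.9 to 1565 ± 50.1 CPM (0.32 ± 0.03), and TOP2B, on chromosome 3 from 25597905 to 25664907, fell (-0.19 ± 0.03). CCND1 rose by 0.34 ± 0.04. CDKN1A (0.05 ± 0.04, adjusted p = 0.239) and RAD21 (0.00 ± 0.03, adjusted p = 0.961) did not pass.

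All 16 luminal genes fell with hormone under ICRF, also adjusted over the list alone, including FOXA1 (-1.99 ± 0.04) and KRT18 (-1.69 ± 0.03). By camera the list had adjusted p = 9.14e-34, and adjusted p = 0.142 with an estimated correlation. Of 25 oestrogen-responsive genes 20 fell and 3 rose (21 and 3 adjusted over the list alone), with STC2 (-2.64 ± 0.04) and CXCL12 (-2.20 ± 0.06) down (camera, adjusted p = 8.07e-18, and adjusted p = 0.142 with an estimated correlation). Of 31 progestin-induced genes 25 rose and 3 fell (26 and 3 adjusted over the list alone), with PDK4 (3.12 ± 0.07), TSC22D3 (2.03 ± 0.05) and FKBP5 (1.27 ± 0.04) up. Camera gave adjusted p = 4.68e-14, and adjusted p = 0.28 with an estimated correlation. Of 33 DNA replication and G1/S genes 20 fell and 4 rose (21 and 4 adjusted over the list alone), with UHRF1 (-1.02 ± 0.06) and MCM7 (-0.77 ± 0.04) down (camera, adjusted p = 0.00149, and adjusted p = 0.564 with an estimated correlation). The mitosis and G2/M genes went both ways, with 11 up, 10 down and 9 not past the threshold of 30, also adjusted over the list alone, a median of -0.02 and a camera adjusted p of 0.73. CDK1, the mitotic kinase, rose (0.51 ± 0.03), and ASPM fell (-0.50 ± 0.04). Of 20 chromatin and cohesin genes 14 fell and 3 rose, also adjusted over the list alone, with STAG1, a cohesin subunit (-0.93 ± 0.04), and the remodeller SMARCA4 (-0.60 ± 0.04) down (camera, adjusted p = 0.0356, and adjusted p = 0.8 with an estimated correlation). Of the 13 mitochondrially encoded messenger RNAs 6 fell and 1 rose, also adjusted over the list alone, with MT-ND1 at -0.59 ± 0.05 (camera, adjusted p = 0.271). In all, 5813 genes were higher and 5572 lower among 18556 tested, and 2587 changed at least 2-fold. The share of higher calls was 51.1%, and 43.7% with upper quartile scaling (median of all genes -0.08 against -0.011). These calls and those of siControl shared 7595 genes, 5473 with the same sign and 2122 with opposite signs, out of 17565 genes tested in both. Both were higher for 2821 genes and both lower for 2652, where independent lists would share 1674 and 1632. Across these genes, which are not independent replicates, the Pearson correlation was 0.567 and the Spearman correlation 0.408.

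**Figure D3:**
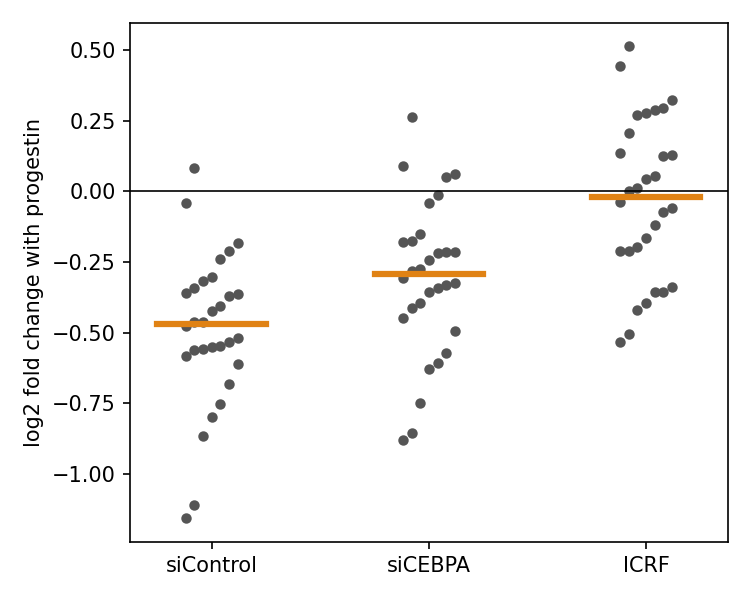
Log2 fold change with progestin of each of the 30 mitosis and G2/M genes (points) in siControl cells, in siCEBPA cells and with ICRF, with the list median as a bar. The medians are -0.47, -0.29 and -0.02, and a line marks 0.

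The difference between the hormone changes with ICRF and in siControl cells was tested over all 12 libraries. The series holds no library without ICRF from the ICRF experiment, and its labels name no siRNA. The difference is therefore between sets of libraries taken as separate experiments, and not of ICRF alone. CEBPA rose less with ICRF, by a log2 difference of -0.79 ± 0.08 (adjusted p = 1.05e-07), as did TSC22D3 (-1.98 ± 0.07), FKBP5 (-1.37 ± 0.05), and DUSP1 (-1.57 ± 0.09). CDKN1A, whose change with ICRF did not pass, also had a negative difference (-0.38 ± 0.06), while AREG, which encodes the growth factor amphiregulin, had a positive difference (2.64 ± 0.12). TOP2A, which fell in siControl cells and rose with ICRF, differed by 0.88 ± 0.08 (adjusted p = 1.25e-07), and RAD21 by 0.34 ± 0.06. TOP2B differed by -0.15 ± 0.06 at an adjusted p of 0.0479, and by -0.001 (adjusted p = 0.99) with no scaling factors. Its call was lost under 8 alternatives in all, upper quartile scaling and single libraries left out among them. PGR (-0.09 ± 0.05, adjusted p = 0.123) and CCND1 (-0.09 ± 0.06, adjusted p = 0.274) did not pass. The largest positive differences included ZNF365 (3.46 ± 0.18), the transcription factor SP4 (3.10 ± 0.12), the cystine transporter SLC7A11 (2.70 ± 0.10) and the kinase NUAK2 (2.73 ± 0.16). The largest negative ones included NES (-4.29 ± 0.21), the small heat shock protein CRYAB (-3.34 ± 0.29), KCNC1 (-3.22 ± 0.19) and EFNA3 (-3.22 ± 0.09).

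Of 16 luminal genes 14 had a negative and 2 a positive difference, also adjusted over the list alone, including KRT19 (-2.31 ± 0.07), CLDN4 (-1.31 ± 0.06) and ESR1 (-2.07 ± 0.06), and the list passed camera (adjusted p = 4.18e-11) also with an estimated correlation (adjusted p = 0.0179). Of 21 cholesterol genes 18 were negative and 1 positive, also adjusted over the list alone, with SQLE (-1.38 ± 0.06) and DHCR7 (-1.02 ± 0.07) negative. The camera test gave adjusted p = 2.31e-07, and adjusted p = 0.107 with an estimated correlation. Of 21 fatty acid genes 10 were negative and 6 positive, also adjusted over the list alone, with SCD (-1.28 ± 0.06) negative and GPAM (1.85 ± 0.08) positive. By camera the list had adjusted p = 0.00573, and adjusted p = 0.0789 with an estimated correlation. Of 30 mitosis and G2/M genes 23 were positive and 1 negative (24 and 1 adjusted over the list alone), such as CDK1 (0.86 ± 0.06), CKAP2L (1.17 ± 0.10) and KIF2C (0.77 ± 0.06), with a list median of 0.41, a camera adjusted p of 9.22e-06 and an adjusted p of 0.431 with an estimated correlation. Of 31 progestin-induced genes 17 were negative and 7 positive (17 and 8 adjusted over the list alone). Camera gave adjusted p = 0.00383, and adjusted p = 0.0789 with an estimated correlation. Of 25 oestrogen-responsive genes 11 were negative and 4 positive, also adjusted over the list alone, with CA12 (-1.67 ± 0.05) and GREB1 (-1.45 ± 0.06) negative (camera, adjusted p = 5.87e-05, and adjusted p = 0.0789 with an estimated correlation). Of 20 chromatin and cohesin genes 13 were negative and 2 positive, also adjusted over the list alone, with STAG1 (-0.97 ± 0.07) and PARP1 (-0.69 ± 0.05) negative. The camera test gave adjusted p = 0.0147, and adjusted p = 0.38 with an estimated correlation. Over 19003 genes, 4729 differences were positive and 4564 negative, and 2534 were at least 2-fold. The share of positive calls was 50.9%, 48.2% with RLE scaling and 65.2% with no scaling factors, under which the median of all genes was 0.17 against 0.02.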

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

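The tests chosen only after the result was seen were that of the untreated libraries between experiments and those of scaling and of a shared processing day for the interferon-stimulated genes. The genes and lists given first stand out because the hormone response differed between groups by a test of the difference itself. The stress gene and interferon patterns weighed after them do not come from that test.

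Between siCEBPA and siControl 1329 genes differed in hormone response. The list medians of the difference were 0.059 for progestin-induced, 0.13 for oestrogen-responsive, 0.16 for DNA replication and G1/S, 0.18 for mitosis and G2/M, 0.38 for C/EBP family, -0.18 for cholesterol and -0.29 for immediate early genes. With an estimated correlation all 7 lists missed the threshold, the smallest adjusted p being 0.321, and with CEBPA left out the C/EBP family list missed it (adjusted p = 0.102). Positive log2 differences were those of GABRQ (2.04), STEAP4 (1.94), PKP1 (1.91), NDRG1 (1.41), S100P (1.31), SGK1 (1.60), PGR (0.69), IGFBP4 (0.96), RERG (0.68), CCND1 (0.42), UHRF1 (0.58), RRM2 (0.41), KIF23 (0.35), MKI67 (0.25), CDKN1A (0.26), CEBPG (0.46), CEBPB (0.55), CEBPA (0.40) and KLF6 (0.57). Negative ones were those of NES (-2.70), ARID5B (-1.65), DUSP6 (-1.45), EFNA3 (-1.35), DUSP1 (-1.34), SPRY2 (-1.26), STARD4 (-0.53), DHCR7 (-0.41) and FOS (-1.48).

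Between ICRF and siControl 9293 genes differed in hormone response. The list medians were -0.38 for progestin-induced, -0.22 for oestrogen-responsive, 0.41 for mitosis and G2/M, -0.27 for fatty acid, -0.48 for cholesterol, -0.67 for luminal and -0.33 for chromatin and cohesin genes. With an estimated correlation the luminal list passed (adjusted p = 0.0179) and the other 6 missed the threshold, at adjusted p of 0.0789 to 0.431. Positive log2 differences were those of ZNF365 (3.46), SP4 (3.10), NUAK2 (2.73), SLC7A11 (2.70), AREG (2.64), CDK1 (0.86), KIF2C (0.77), CKAP2L (1.17), GPAM (1.85), RAD21 (0.34) and TOP2A (0.88). Negative ones were those of NES (-4.29), CRYAB (-3.34), KCNC1 (-3.22), EFNA3 (-3.22), TSC22D3 (-1.98), FKBP5 (-1.37), DUSP1 (-1.57), ESR1 (-2.07), CA12 (-1.67), GREB1 (-1.45), CEBPA (-0.79), SCD (-1.28), SQLE (-1.38), DHCR7 (-1.02), KRT19 (-2.31), CLDN4 (-1.31), STAG1 (-0.97), PARP1 (-0.69), TOP2B (-0.15, but -0.001 with no scaling factors) and CDKN1A (-0.38).

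Mitosis and G2/M genes fell with hormone in siControl and went both ways with ICRF. With an estimated correlation the list missed the threshold in siControl (adjusted p = 0.729) and for the difference (adjusted p = 0.431). The smallest list median of the difference under the other scalings was 0.38, which argues against scaling as the whole cause. The deepest siControl untreated library is also argued against, since without it the siControl list median was -0.53. What stays open is whether ICRF or another difference between the 2 experiments is the source, because 29 of the 30 genes were already higher in ICRF untreated than in siControl untreated libraries (list median 0.79) and the series holds no library without ICRF from that experiment. ICRF and the experiment cannot be told apart here.

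Unfolded protein and amino acid stress genes were lower after CEBPA siRNA, in 15 of 19 untreated and 17 of 19 treated. With an estimated correlation the list missed the threshold (adjusted p = 0.118 untreated and 0.202 treated). The highest list median under the other scalings was -0.50, which argues against scaling as the whole cause. Without the siCEBPA libraries numbered 2, the highest list median was -0.59, which argues against these libraries as the cause. This setting was added after the data were seen. An effect of the siRNA other than on CEBPA cannot be told apart from a loss of C/EBPα, since the labels name only 1 siRNA against CEBPA, and CEBPB also fell in untreated cells (log2 change -1.45).

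Interferon-stimulated genes were higher in the siCEBPA libraries numbered 2 than in those numbered 1. A scaling factor moves the list and all genes of a library alike, so trying several scalings could not change the gap between them. The gap itself, at least 0.84 above the median of all genes, argues against scaling as the cause. A processing day shared by every siRNA library numbered 2 is argued against by the lowest siControl list median, -0.23. A cause limited to the siCEBPA libraries numbered 2 stays open, and no biological explanation was tested.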

How the results depend on the processing

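Chosen after the data were seen were the settings with no scaling factors, with thinned counts, with both siCEBPA libraries numbered 2 left out and with CEBPA left out of the C/EBP family list. The named genes made 213 values, a gene named in several comparisons counting once in each. Under the alternatives 3171 of their values kept direction and side of the threshold, 30 lost the call, 15 gained one and 23 reversed, and none of the shared calls of any comparison changed sign. At a change of at least 2-fold the counts were 3039 and 3062 for the hormone in siControl and siCEBPA, 129 for their difference, 1248 and 1209 for the knockdown, 2587 with ICRF and 2534 for the ICRF difference, and the overlaps of the same sign were 2172, 995 and 1022, because fewer genes pass. Of 44 list tests past the threshold 3 were left with an estimated correlation. That run also rests on few residual degrees of freedom, so these losses cannot be laid to correlation between genes alone. With CEBPA left out of its list 41 were left, the C/EBP family list losing its call with hormone in siControl (adjusted p = 0.17), in siCEBPA (0.0523) and for their difference (0.102).

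The difference between siCEBPA and siControl ranged from 692 to 1381 genes when 1 replicate was left out, from 1329, and was 692 and 779 without siControl progestin replicate 1 and 2. A lone library is then assumed to vary like the other groups. The replicate number as a block gave 2271 genes for this difference. It raised the calls from 10741 to 11403 for the hormone in siControl and from 10685 to 11349 in siCEBPA. For the knockdown they rose from 8558 to 9493 in untreated and from 8192 to 9088 in treated cells. Deviations of libraries with the same number correlated at 0.011 to 0.092 in the siRNA groups and 0.014 in the ICRF groups. The siRNA libraries were treated as sharing only a number, although both siCEBPA libraries numbered 2 have higher interferon-stimulated genes than those numbered 1.

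For the genes higher with hormone under ICRF the median difference was 0.007, -0.004 with a mean of at least 5 CPM, 0.081 for changes of at least 2-fold, and -0.003 to 0.020 with a replicate left out. For the genes lower with hormone under ICRF it ran from 0.037 to 0.056. Before adjustment over the 2 sets fry lost its call only without siControl progestin replicate 1, where the median difference was 0.039. After that adjustment it was also lost without 4 other libraries, named in the report.

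The 30 lost calls were, by number of alternatives, those of TOP2B (8) in the ICRF difference, CEBPA and MKI67 (5 each), CDKN1A (4), CEBPB (3), UHRF1, RRM2 and KIF23 (1 each) in the difference between siCEBPA and siControl, RAD21 (1) in the knockdown in untreated and TOP2A (1) in that in treated cells. In the siCEBPA difference these were MKI67 (0.21) without siControl untreated replicate 1, and CDKN1A (0.212), CEBPB (0.468) and CEBPA (0.294) without replicate 2. Without siControl progestin replicate 1 they were UHRF1 (0.497), RRM2 (0.354), KIF23 (0.307), MKI67 (0.185), CDKN1A (0.25) and CEBPA (0.401), and without replicate 2 CDKN1A (0.269), CEBPB (0.515) and CEBPA (0.386). CEBPA also lost it without siCEBPA untreated replicate 1 (0.312) and siCEBPA progestin replicate 2 (0.347), and MKI67 without siCEBPA untreated replicate 2 (0.227) and with all 12 libraries in the fit (0.248). Without both siCEBPA libraries numbered 2, MKI67 (0.22), CDKN1A (0.225) and CEBPB (0.48) lost it. TOP2B in the ICRF difference lost it with upper quartile factors (-0.113), no filter (-0.126), no scaling factors (-0.001), and without ICRF untreated replicate 1 (-0.17) or 2 (-0.14), ICRF progestin replicate 1 (-0.173), siControl untreated replicate 2 (-0.117) or siControl progestin replicate 2 (-0.113). RAD21 lost it with no scaling factors (-0.107), and TOP2A without siControl progestin replicate 1 (0.217).

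Single genes whose value reversed had all missed the threshold. With a replicate left out, TOP2B ran from -0.067 to 0.019 (0.016 among them) with hormone in siControl, from -0.077 to 0.063 (0.036) in siCEBPA and from -0.049 to 0.091 (-0.013, -0.020, -0.009) for their difference, TOP2A from -0.058 to 0.109 (-0.046) for the knockdown in untreated cells, CCND1 from -0.038 to 0.093 (-0.001) for that in treated cells and RAD21 from -0.021 to 0.031 (-0.003) with ICRF. TOP2B in siCEBPA was 0.004 with RLE factors and with DESeq2, 0.007 with no filter and 0.032 without both siCEBPA libraries numbered 2. With upper quartile factors and ICRF, CDKN1A was -0.015 and RAD21 -0.067, and RAD21 was -0.034 with a mean of at least 5 CPM. With no scaling factors CCND1 was 0.068 and PGR 0.063 in the ICRF difference. Apart from the smaller sets of genes or libraries these settings use, the cause was not tested.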

Other observations

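The untreated ICRF and siControl libraries differed at 12279 of 19003 genes (64.6%), which compares experiments and not ICRF alone. No list test was run on this comparison, so the list values that follow are medians of the log2 change and counts of called genes. The interferon-stimulated list had a median of -1.38, with 16 of 28 genes lower and none higher in the ICRF libraries, and the unfolded protein and amino acid stress list one of -0.48, with 13 of 19 lower and 4 higher. The basal and myoepithelial list had a median of 1.16, with 10 of 13 higher and 1 lower, and the DNA replication and G1/S list one of 0.25, with 19 of 33 higher and 3 lower. The progestin-induced list had a median of -0.39, with 18 of 31 lower and 7 higher.

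Ribosomal protein genes held 3.47% to 3.648% of the counts in the siCEBPA libraries, 4.145% to 4.471% in the siControl libraries and 4.523% to 4.66% in the ICRF libraries. MALAT1 and NEAT1 together held 0.03% and 0.04% in siControl untreated and 0.02% and 0.022% in siControl progestin libraries, 0.038% and 0.049% in siCEBPA untreated and 0.021% and 0.023% in siCEBPA progestin libraries, and 0.016% and 0.017% in ICRF untreated and 0.01% and 0.011% in ICRF progestin libraries. These shares were not tested.

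The test of CEBPA against the untreated siControl level was chosen only after the result was seen. Most hormone calls were shared after CEBPA siRNA, with 8751 genes called with the same sign in siControl and siCEBPA cells. A candidate explanation is that the hormone raised CEBPA in siCEBPA cells above the untreated siControl level. CEBPA in siCEBPA progestin cells was higher than in siControl untreated cells by a log2 change of 0.23 (1.17-fold, adjusted p = 0.00681). This leaves the hypothesis open and does not test it, because no library without CEBPA exists in the series.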
